A study of Mus musculus with 8 samples.

How the data were processed

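RNA was measured in CD4+ CD8+ (double-positive) thymocytes of C57BL/6J and NOD/ShiLtJ (NOD) mice. Per the labels' protocols, thymi were pressed through a mesh, the suspension was stained for viability, CD4 and CD8a, live single double-positive cells were sorted by flow cytometry, and total RNA was made into stranded libraries from a small input and sequenced as short paired-end reads. The set holds 8 libraries, 4 per strain, and each title carries a B number and a T number that the labels do not spell out. The libraries that shared a strain and a B number were summed, which left 4 samples, 2 per strain, so that repeated libraries of 1 sample would not inflate the number of samples. Nothing in the labels says that the B numbers are separate animals, so the p-values measure only the spread between these samples, which may be technical.

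The authors deposited 1 table of raw counts per library, whole numbers of reads per Ensembl gene without normalization. Per the submitters' processing notes, reads were aligned to the mouse genome build GRCm38 with STAR 2.5.0a and counted with HTSeq 0.6.1; the annotation release, the strand setting, read filters and duplicate removal were not given in the sources used here. Each table listed 53465 genes, of which 53360 had an identifier in GENCODE M21, the annotation used for symbols, gene types and coordinates (GRCm38), and 105 had none. The deposited counters for reads with several alignments, low-quality reads and unaligned reads were all 0, and every mitochondrially encoded gene had 0 counts in every library, so these tables cannot show those classes. Between 39.98% and 59.1% of the reads listed per library fell outside annotated genes, and these were not used.

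The reads in genes came to 8.527 to 15.702 M per C57BL/6J library and 23.533 to 30.371 M per NOD library. The summed samples held 23.81 and 24.229 M reads in genes for C57BL/6J samples 1 and 2, and 47.237 and 55.647 M for NOD samples 1 and 2. A gene with 0 counts in all samples of a strain was given a floor of 3 counts over the strain, and its fold is a lower bound. For genes with 1 to 3 counts in a strain the ratio was given with an exact 95% interval of the 2 counts. Intervals and floors cover counting error only, since the reads carried no molecular identifiers. Counts per M (CPM) are given as mean ± SD of the 2 summed samples of a strain, and log2 fold changes (NOD over C57BL/6J) with their standard error (SE).

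Genes were kept with the edgeR function filterByExpr, scaled by TMM factors and tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust, strain as the only term, 2 residual degrees of freedom) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. On simulated data with 2 samples against 2, this fit called 1.4% of genes changed 1.5-fold, 21.5% of genes changed 2-fold, 68.2% of genes changed 4-fold and 93.3% of genes changed 8-fold when each gene had its own dispersion (16845 genes), with 16.2% of calls false and 4.8% of unchanged genes at an unadjusted p under 0.05. With trended dispersions (16914 genes) it called 4.1%, 27.6%, 76.7% and 96% at the same folds, with 3.8% of calls false and 4.87% of unchanged genes at an unadjusted p under 0.05. These shares cover all simulated calls and also depend on how many genes were set to change. The share of false ones among the calls made here is therefore uncertain.

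A total of 35 gene lists were fixed, covering thymocyte stages, T cell receptor signalling, interferon and antigen presentation, diabetes candidates of the NOD mouse, gene families, metabolism, markers of other cells, and checks of strain and sex; their results are all in the report. The 31 with 5 or more tested members, checks aside, were tested with camera in limma 3.58.1 (preset correlation 0.01) on voom log2 CPM, and again with a correlation estimated for each list. The fry test asked whether the members of a list moved on balance in 1 direction, and its mixed form whether they changed in either direction; neither compares the list with other genes. Fisher's exact test compared the share of called genes in each list with that of all other tested genes. On simulated data, camera called 20 of 20 lists shifted 1.5-fold and 0 of 20 unshifted lists over the same 17291 genes. The simulated genes varied independently, so this does not give the rate of false calls for lists whose members vary together. The estimated correlation reached 0.967, for the proliferation list.

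For position, the 11791 tested protein-coding genes were ordered by start, and the number of adjacent pairs with both genes called was compared, one-sided, with 10000 random reassignments of the calls within 10 bins of mean expression. On simulated call sets this test gave p under 0.05 for 1 of 20 random sets and for 20 of 20 sets with pairs placed side by side. The share of called genes on each chromosome was compared with all other chromosomes by Fisher's exact test, two-sided and adjusted over chromosomes.

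Named genes were the 12 with the largest increase and the 12 with the largest decrease among called genes annotated as protein-coding, with mean CPM of 10 or more, all 4 libraries of 1 strain above all 4 of the other, and a symbol that is not a clone or predicted name. Added to these were up to 4 called members of each list with the smallest adjusted p (the most abundant members, up to 2, where fewer than 2 were called), every called diabetes candidate, and Nnt, Xist, Ddx3y, Cd4, Cd8a, Rag1, Cd3e, H2-K1 and H2-D1. The grouping, tests, lists, this rule and most alternatives were chosen before the data were examined.

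The alternatives were DESeq2 (1.42.0) size factors and its Wald test, upper-quartile factors, no count filter, mean CPM of 5 or more, the 8 libraries as separate samples or with limma's duplicateCorrelation, the libraries of 1 T number only, a replicate block on the B number, a minimum fold of 1.5, a threshold of 0.01, protein-coding genes only, and leaving out each summed sample in turn. After the data were seen, thinning to equal totals, a covariate for the percent of reads outside genes, leaving out the 2 libraries with the lowest such percent, a crossed pairing, and leaving out overlapping genes were added. Tables were joined with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.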

Results

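The transcriptomes of sorted CD4+ CD8+ thymocytes, the double-positive stage at which T cell precursors rearrange the alpha chain of the T cell receptor and undergo selection, were compared between C57BL/6J mice and NOD mice, an inbred strain that develops autoimmune diabetes spontaneously. The series concerns how genetic variants of type 1 diabetes relate to the folding of chromatin in T cells, and its RNA part asks which genes differ in expression between the strains. There were 4 libraries per strain, summed into 2 samples per strain. The NOD libraries were sequenced more deeply than the C57BL/6J libraries. They held 23.533 to 30.371 M reads in genes against 8.527 to 15.702 M. The share of reads outside annotated genes was 39.98% to 53.9% in C57BL/6J libraries and 46.6% to 59.1% in NOD libraries.

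Marker genes of the sorted stage were abundant in both strains. Cd4 stood at 1251 ± 159 CPM in C57BL/6J and 1293 ± 66.4 CPM in NOD (mean ± SD, n = 2 summed samples per strain here and below), with an adjusted p of 0.953 in edgeR. Cd8a stood at 1563 ± 120 and 1660 ± 30.04 CPM (adjusted p = 0.910), and Cd3e, a chain of the T cell receptor complex, at 727 ± 107 and 954 ± 54.5 CPM (adjusted p = 0.409). Rag1, a subunit of the recombinase that joins receptor segments, stood at 8998 ± 796 CPM in C57BL/6J and 5902 ± 950 CPM in NOD (adjusted p = 0.217), lower in all 4 NOD libraries. Of the 30 tested genes of the double-positive identity list, 1 passed the test, or 0 adjusted over the list alone: Ly6d, a surface antigen of early lymphocytes, was lower in NOD (log2 fold change -0.74 ± 0.17 SE, adjusted p = 0.0488). Its adjusted p was 0.401 without C57BL/6J sample 1, 0.114 without C57BL/6J sample 2, 0.0510 without NOD sample 2 and 0.0954 with the replicate block. The identity list did not shift in 1 direction (camera, adjusted p = 0.856; median log2 fold change 0.06, mean -0.004, test direction down), while fry gave an adjusted p of 0.00744 for change in either direction, which 20 of the 31 lists passed. Nnt, the mitochondrial transhydrogenase of which C57BL/6J carries a known internal deletion, was higher in NOD (0.81 ± 0.18, adjusted p = 0.0410), from 60.2 ± 10.2 to 106 ± 5.04 CPM and with all 4 NOD libraries above all 4 C57BL/6J libraries. That adjusted p was 0.384 without C57BL/6J sample 1, 0.0761 without C57BL/6J sample 2 and 0.0797 with the replicate block.

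Single genes differed widely between the strains. H2-T3, a nonclassical class I gene that encodes the thymus leukemia antigen (ENSMUSG00000054128, chromosome 17, 36185572 to 36190287), rose from 0.551 ± 0.0335 CPM in C57BL/6J to 372 ± 97.0 CPM in NOD, a log2 fold change of 9.39 ± 0.31 (adjusted p = 3.15e-06). Slamf1, which encodes the lymphocyte receptor CD150 and is a diabetes candidate of the NOD mouse (ENSMUSG00000015316, chromosome 1, 171767127 to 171801184), fell from 120 ± 8.71 to 11.7 ± 2.92 CPM (log2 fold change -3.36 ± 0.22, adjusted p = 5.97e-05). Trim12a, a mouse relative of the antiviral restriction factor TRIM5 (ENSMUSG00000066258, chromosome 7, 104299894 to 104315466), fell from 82.6 ± 12.4 to 0.0701 ± 0.0492 CPM (-10.19 ± 0.38, adjusted p = 3.41e-06). Tdrd5, a tudor-domain gene of the germline piRNA pathway (ENSMUSG00000060985, chromosome 1, 156255296 to 156303664), fell from 284 to 18.03 CPM (-3.98 ± 0.20, adjusted p = 1.09e-05). In each of these genes all 4 libraries of 1 strain lay above all 4 of the other, which the rule that named them required.

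Of 17291 tested genes, 637 (3.68%) passed an adjusted p of 0.05 in edgeR, 330 higher and 307 lower in NOD. Protein-coding genes made up 213 of the higher and 184 of the lower genes. A change of at least 2-fold was found in 313 of the higher and 281 of the lower genes, and of at least 4-fold in 237 and 191. The libraries of the strains did not overlap for 634 of the 637 genes (99.5%), against 17.03% of all tested genes. The 637 genes were called on sums of the same libraries, so this separation is not independent evidence for the calls. Random order of the libraries would give 2.86%, but that figure treats libraries sharing a B number as independent. Their consensus correlation was 0.443 (duplicateCorrelation), so 2.86% may be too low, and no conclusion was drawn from it. Of the called genes, 55 had 0 counts in 1 strain, so their fold is known only as a bound. The number of called genes was 256 without C57BL/6J sample 1, 359 without C57BL/6J sample 2, 1389 without NOD sample 2 and 513 with the replicate block, and none of the 637 changed direction in any of the fits in which it was tested.

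Among the 12 protein-coding genes with the largest increase in NOD under the naming rule, Epha2, an ephrin receptor tyrosine kinase, rose from 0.145 to 89.4 ± 14.7 CPM (log2 fold change 9.21 ± 0.35). Ryr2, the ryanodine receptor of the heart, rose from 0.0847 to 43.0 ± 7.97 CPM (8.94 ± 0.38). Zfp979, a zinc finger gene on chromosome 4, had 1 count in C57BL/6J and 3743 in NOD, a ratio of 1696 with a counting interval of 304.3 to 67020. Cadm4, a cell adhesion molecule, rose by 5.60 ± 0.37 on the log2 scale and Greb1, an oestrogen-responsive cofactor gene, by 5.27 ± 0.27. Trim16, a ubiquitin ligase gene that overlaps the protein-coding gene Fbxw10, rose by 4.596 ± 0.28 and the forkhead gene Foxb1 by 4.58 ± 0.33. Prag1, a pseudokinase scaffold, rose from 5.78 to 93.4 CPM. Alpk1, the kinase that senses bacterial ADP-heptose, rose from 2.33 to 36.8 CPM. Rdh10, a retinol dehydrogenase of retinoic acid synthesis, rose from 5.68 to 78.0 CPM. Rapgef4, the cyclic AMP sensor EPAC2, rose from 4.78 to 49.5 CPM. Their adjusted p-values were at most 0.000184, and each of the 12 stayed past the threshold in every fit in which it was tested. Of the 58 named genes that passed, 24 overlapped another gene with counts, 5 of these a protein-coding gene, and 38 stayed past the threshold in every fit in which they were tested.

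Among the 12 protein-coding genes with the largest decrease under the same rule, Eps8l1, an actin-regulating gene, fell from 29.5 to 0.0717 CPM (log2 fold change -8.70 ± 0.69), and Rab6b, a small GTPase of Golgi traffic, fell from 53.9 to 0.228 CPM (-7.90 ± 0.38). Slc15a2, a peptide transporter, fell from 52.9 ± 44.8 to 0.135 CPM (-8.59 ± 1.04, adjusted p = 0.0319), and its adjusted p was 0.853 without NOD sample 1 and 0.573 without NOD sample 2. Dapk1, a death-associated kinase, fell from 92.9 to 2.02 CPM (-5.52 ± 0.25), and Hist1h4m, a histone H4 gene, fell from 25.7 to 0.698 CPM (-5.19 ± 0.35). Map7, a microtubule-binding protein, fell from 40.9 to 2.58 CPM (-3.98 ± 0.31). Tns3, an adaptor of focal adhesions, fell from 40.2 to 3.40 CPM, Epsti1, an interferon-inducible gene, from 230 to 19.6 CPM, and Sqor, the mitochondrial sulfide oxidase, from 21.7 to 2.17 CPM. Apart from Slc15a2, the adjusted p-values of the 12 were at most 0.000765.

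**Figure D1:**
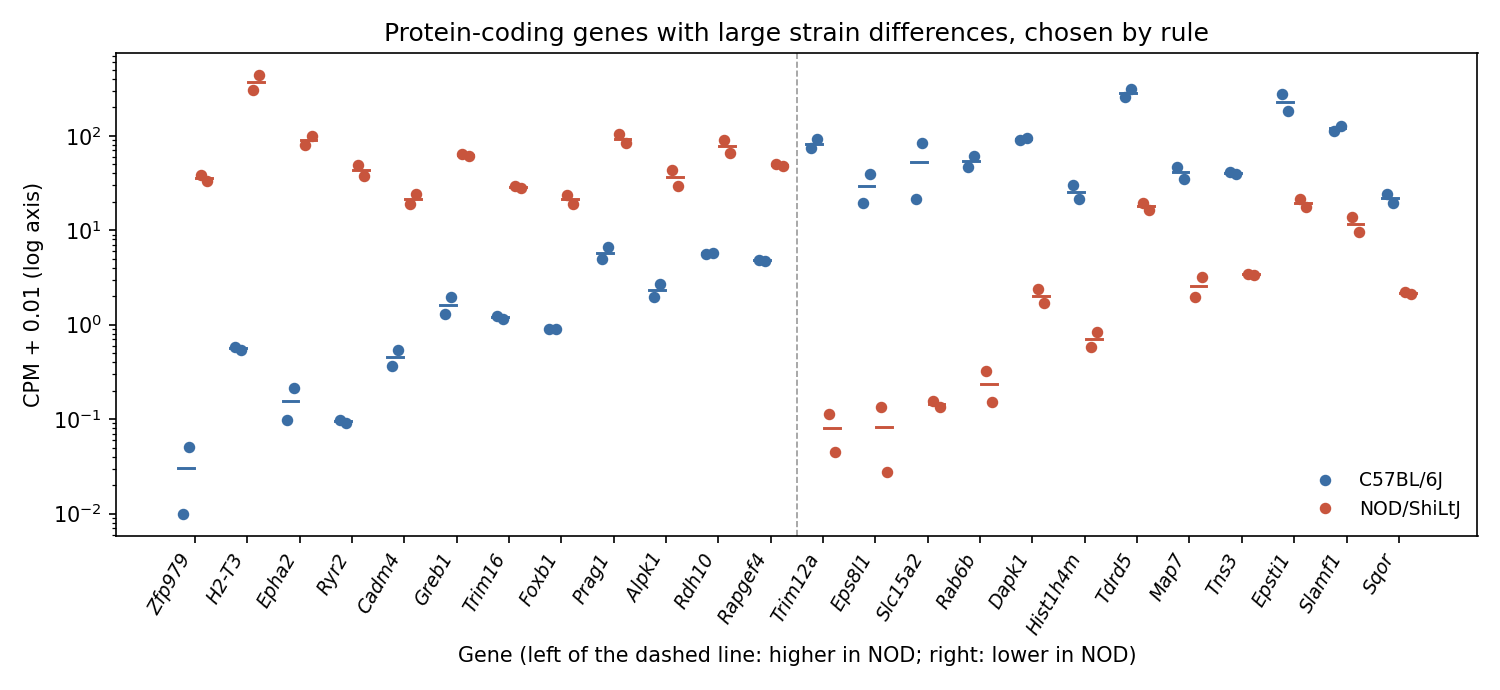
Level in CPM plus 0.01 (logarithmic axis) of the 12 protein-coding genes with the largest increase and the 12 with the largest decrease in NOD under the naming rule, one point per summed sample, with bars at the mean of each strain (blue, C57BL/6J; red, NOD). The samples of the strains do not overlap for any of these genes, because the naming rule required this of their libraries.

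Diabetes candidates of the NOD mouse changed in single genes. Of the 40 tested candidates, 2 were higher and 3 lower in NOD, and 7 and 6 when adjusted over the list alone. Beside Slamf1, Ubash3a, a negative regulator of T cell receptor signalling, fell from 96.9 ± 0.988 to 48.0 ± 1.96 CPM (log2 fold change -1.01 ± 0.16, adjusted p = 0.00880). Cd93, a C-type lectin-like receptor, fell from 3.22 to 0.419 CPM (-2.91 ± 0.61, adjusted p = 0.0346). Clec2d, a lectin ligand of NK cell receptors, rose from 48.9 to 102 CPM (1.05 ± 0.17, adjusted p = 0.0108), and Clec16a, an autophagy gene of a human diabetes locus, rose from 58.3 to 96.3 CPM (0.72 ± 0.16, adjusted p = 0.0473). The strains' libraries did not overlap for any of the 5. Without C57BL/6J sample 1 the adjusted p was 0.0738 for Ubash3a, 0.223 for Cd93, 0.121 for Clec2d and 0.384 for Clec16a, and without C57BL/6J sample 2 it was 0.0583, 0.137, 0.0614 and 0.187; for Clec16a it was also 0.0701 without NOD sample 1 and 0.114 with the replicate block. As a set the candidates did not move in 1 direction (camera, adjusted p = 0.888; median -0.07, mean 4e-04, test direction down), and their share of called genes, 12.5%, did not pass the test against other genes (Fisher's exact test, adjusted p = 0.121). In the SLAM family 1 of 8 genes passed, Slamf1, or 2 higher and 2 lower adjusted over the list alone, and the family did not move together (adjusted p = 0.839; median 0.16, mean -0.06, test direction down). Cd84, its most abundant member, stood at 147 and 180 CPM (adjusted p = 0.629).

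Class I genes of the major histocompatibility complex (MHC), which present peptides to CD8+ T cells or serve as ligands of innate-like lymphocytes, differed in the nonclassical members. Of 26 tested genes of the list, 6 were higher and 0 lower in NOD (23.1%), and 8 and 1 when adjusted over the list alone, a larger share than among the other tested genes (Fisher's exact test, adjusted p = 0.00957). Beside H2-T3, H2-T10 rose from 13.0 to 178 CPM (log2 fold change 3.78 ± 0.21, adjusted p = 1.84e-05) and H2-T22 from 20.2 to 49.1 CPM (1.28 ± 0.21, adjusted p = 0.0111). Both encode class I-like molecules recognised by gamma-delta T cells, and H2-T10, annotated as a polymorphic pseudogene, overlaps BC023719, which went from 0.0626 to 32.1 CPM, and Gm7030. H2-Bl, also annotated as a polymorphic pseudogene, had 3 counts in C57BL/6J and 2329 in NOD, a ratio of 351.8 with a counting interval of 120.2 to 1707. The classical genes did not pass the test, with H2-K1 at 24.3 and 18.6 CPM (adjusted p = 0.594) and H2-D1 at 76.7 and 63.2 CPM (adjusted p = 0.626). Class I genes exist in similar copies, and Gm8810, Gm8815 and Gm5682 of the same region went from 0 to 1.67, 1.42 and 8.84 CPM. A strain difference in 1 gene was not separated from NOD reads assigned to another copy of the reference or lost, the classical genes included. Fisher's exact test also counted these neighbouring genes as independent. The list rose with camera (adjusted p = 0.0181; median 0.18, mean 1.22), with adjusted p = 0.712 with an estimated correlation and 0.191 without C57BL/6J sample 2, a sample whose loss also took H2-T22 to 0.0992. Class II genes, markers here of antigen-presenting cells, were low, and none of 11 passed the test (2 higher and 0 lower adjusted over the list alone). Cd74, the invariant chain, stood at 10.4 and 18.7 CPM (adjusted p = 0.120) and H2-Oa at 10.9 and 7.92 CPM (adjusted p = 0.770). The class II list rose with camera (adjusted p = 0.0128; median 0.65), with adjusted p = 0.712 with an estimated correlation, 0.236 without C57BL/6J sample 2 and 0.314 without NOD sample 2.

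Interferon-inducible genes changed in both directions. Of 60 tested, 2 were higher and 5 lower in NOD, the same numbers adjusted over the list alone (11.7%; Fisher's exact test, adjusted p = 0.0675), and the list did not move in 1 direction (camera, adjusted p = 0.582). Most of the changed genes belong to the Ifi200 cluster of DNA sensors on chromosome 1. Ifi203 rose from 31.6 to 129 CPM (log2 fold change 2.03 ± 0.18, adjusted p = 0.000360), while Ifi206 (-3.64 ± 0.39, adjusted p = 0.000976), Ifi209 (-2.38 ± 0.29, adjusted p = 0.00306) and Ifi213 (-4.06 ± 0.60, adjusted p = 0.00577) fell. Ifi203 overlaps Mndal, a related gene of the cluster. None of the 7 tested Schlafen genes, an interferon-linked family, passed the test or did so adjusted over the list alone (adjusted p = 0.900 for the list), with Slfn2 at 134 and 114 CPM and Slfn9 at 26.5 and 35.4 CPM (adjusted p = 0.823; 0.00854 without NOD sample 1).

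GIMAP genes, most of them small GTPases that sustain lymphocyte survival, were lower in NOD as a list with camera at its preset correlation. Of 9 tested, 0 were higher and 1 lower (Gimap1os, not annotated as protein-coding), and 0 and 5 adjusted over the list alone. The list fell with camera (adjusted p = 0.000216; median log2 fold change -0.48, with 8 of 9 members negative and Gimap9 at 0.00), with adjusted p = 0.712 with an estimated correlation. Gimap1os, a transcript opposite Gimap1, fell from 24.3 to 2.25 CPM (-3.44 ± 0.29, adjusted p = 0.000284), and Gimap6, the most abundant coding member, stood at 233 ± 11.6 and 143 ± 21.1 CPM (adjusted p = 0.0659; 0.0104 without NOD sample 1).

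Few genes of T cell receptor signalling passed the test. None of 30 genes induced by receptor signals passed the test, and 0 did adjusted over the list alone, with Cd28 at 283 and 308 CPM and Cd6 at 190 and 205 CPM. The list rose with camera (adjusted p = 0.0129; median 0.18), with adjusted p = 0.712 with an estimated correlation and 0.155 without NOD sample 1. Of 31 signalling components, Ubash3a alone passed (1 adjusted over the list alone), and the list did not move (adjusted p = 0.900; median -0.03, mean 0.02, test direction down). Ptprc, the phosphatase CD45, stood at 2019 and 1937 CPM. Among 19 costimulation and checkpoint receptors, 2 were higher and 0 lower, and 3 and 1 adjusted over the list alone. Cd200, an inhibitory ligand, rose from 1.99 to 10.4 CPM (2.39 ± 0.33, adjusted p = 0.00428), and Tnfrsf14, the receptor HVEM, rose from 10.5 to 24.3 CPM (1.22 ± 0.23, adjusted p = 0.0200; 0.144 without C57BL/6J sample 1 and 0.135 without C57BL/6J sample 2). The receptor list rose with camera (adjusted p = 0.0308; median 0.33), with adjusted p = 0.712 with an estimated correlation, 0.0722 without C57BL/6J sample 2 and 0.229 without NOD sample 1. The mature single-positive markers, a later thymocyte stage, stood beside the receptor-signal and costimulation lists at a mean log2(CPM + 1) of 2.68 to 2.81 in the C57BL/6J libraries and 3.00 to 3.08 in the NOD libraries (camera, adjusted p = 0.0797). All 3 lists stood higher in both libraries of NOD sample 1 than in those of NOD sample 2.

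Few adhesion and survival genes passed the test. Of 22 chemokine receptors and adhesion genes, 2 were higher and 0 lower (2 and 1 adjusted over the list alone), and the list did not move (camera, adjusted p = 0.839; median -0.05, mean 0.15, test direction up). Itga6, the integrin alpha 6 chain that binds laminin, rose from 122 ± 6.83 to 409 ± 5.07 CPM (log2 fold change 1.75 ± 0.16, adjusted p = 0.000453). Cd44, the hyaluronan receptor, rose from 11.9 to 24.1 CPM (1.02 ± 0.23, adjusted p = 0.0474; 0.361, 0.174 and 0.129 without C57BL/6J sample 1, C57BL/6J sample 2 and NOD sample 1, and 0.106 with the replicate block). None of 28 apoptosis regulators passed (camera, adjusted p = 0.139; 0.0315, up, without C57BL/6J sample 1), with Mcl1 at 325 and 358 CPM and Bcl2l1 at 257 and 251 CPM. None of 17 genes of the glucocorticoid response passed (1 higher adjusted over the list alone; camera, adjusted p = 0.369), with Btg1 at 418 and 481 CPM and Txnip at 350 and 372 CPM. None of 26 NF-kappaB genes passed (camera, adjusted p = 0.428), with Tnfaip8 at 187 and 272 CPM (adjusted p = 0.256; 0.0159 without NOD sample 2) and Tnfaip3 at 194 and 173 CPM. None of 32 cytokine receptor and signalling genes passed (camera, adjusted p = 0.733; median -0.03, mean 0.04, test direction down), with Jak1 at 571 and 526 CPM and Ifngr1 at 481 and 416 CPM. For apoptosis, NF-kappaB and cytokine genes, 0 passed adjusted over the list alone.

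Proliferation genes were low in 1 of the 2 NOD samples. Mki67, a marker of cycling cells, stood at 1590 and 2127 CPM in the C57BL/6J samples, at 326 CPM in NOD sample 1 and at 2070 CPM in NOD sample 2 (log2 fold change -0.63 ± 0.91, adjusted p = 0.879; without NOD sample 2, -2.52 and adjusted p = 1.07e-14). None of 40 tested proliferation genes passed the test, and 0 did adjusted over the list alone. The list fell with camera (adjusted p = 0.000216; median -0.40), with adjusted p = 0.733 with an estimated correlation, and without NOD sample 1 it rose (adjusted p = 0.00779). Against the mean of the C57BL/6J samples, the median log2 difference of the 40 genes was -1.47 in NOD sample 1 and 0.21 in NOD sample 2, and all 40 were lower in NOD sample 1 than in NOD sample 2. Ccnd3, the D-type cyclin of the beta-selection burst, stood at 808 ± 22.7 and 1202 ± 32.9 CPM (adjusted p = 0.119) and was the member that did not have its lowest level in NOD sample 1.

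**Figure D2:**
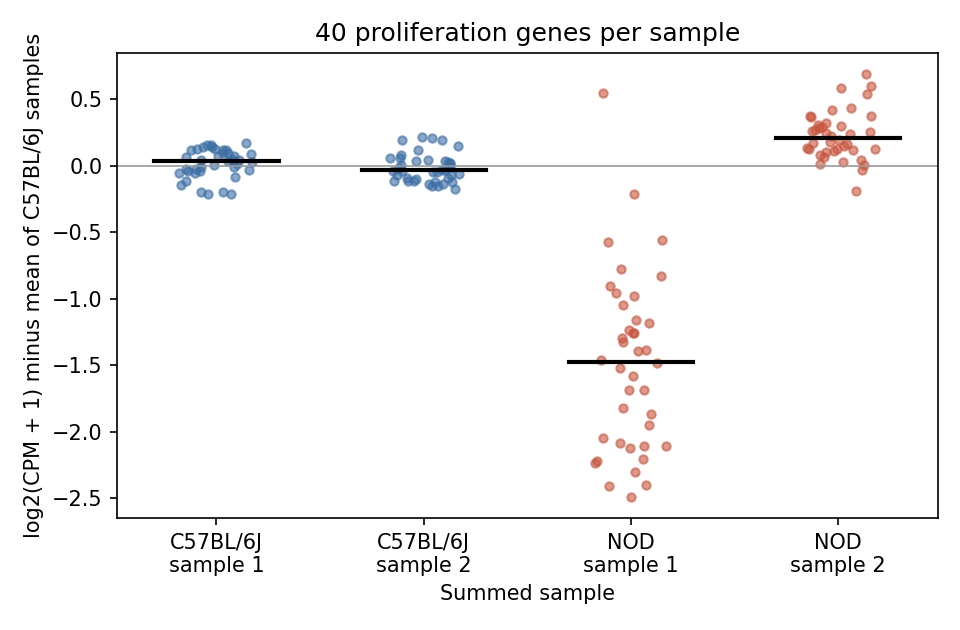
Difference of log2(CPM + 1) from the mean of the C57BL/6J samples for 40 proliferation genes, with one point per gene in each summed sample and a bar at the median. The median lies at -1.47 in NOD sample 1 and at 0.21 in NOD sample 2.

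Histone genes that are transcribed in S phase differed by member. Of 68 tested, 4 were higher and 4 lower in NOD, and 6 and 4 adjusted over the list alone. Hist1h2al, a histone H2A gene annotated as a processed pseudogene, rose from 4.79 to 746 ± 269 CPM (log2 fold change 7.28 ± 0.32, adjusted p = 9.35e-06), while Hist1h4m, Hist3h2ba (-3.05 ± 0.25, adjusted p = 0.000217) and Hist1h3f (-2.89 ± 0.31, adjusted p = 0.00244) fell. For these members a strain difference was not separated from NOD reads assigned to another histone gene of the reference or lost. The list fell with camera (adjusted p = 0.0269; median -0.20), with adjusted p = 0.911 with an estimated correlation. Its adjusted p was 0.572 without C57BL/6J sample 1, and without NOD sample 1 it rose (adjusted p = 0.00144). None of 36 genes of chromatin folding passed the test, and 0 did adjusted over the list alone, with Satb1, an organiser of thymocyte chromatin, at 5852 ± 473 and 4885 ± 624 CPM (adjusted p = 0.718) and Tcf7, the transcription factor TCF-1, at 4027 ± 126 and 3200 ± 199 CPM (adjusted p = 0.544). That list fell with camera (adjusted p = 0.0339; median -0.16), with adjusted p = 0.712 with an estimated correlation, 0.176 without C57BL/6J sample 2 and 0.804 without NOD sample 1. Both lists were measured beside the low proliferation genes of NOD sample 1 (median -1.47), and the chromatin list shares Top2a with that list.

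Numbered zinc finger genes, many of which encode repressors of transposable elements, included genes with almost no counts in 1 strain. Of 331 tested, 12 were higher and 3 lower, and 13 and 3 adjusted over the list alone. Beside Zfp979, 2 more genes of chromosome 4, Zfp990 (log2 fold change 6.35 ± 0.51, from 0.105 to 8.85 CPM, adjusted p = 0.000193) and Zfp985 (4.36 ± 0.58, adjusted p = 0.00348), rose. Zfp125, annotated as a pseudogene, had 349 counts in C57BL/6J and 2 in NOD, a ratio of 385.0 with a counting interval of 105.8 to 3192. For these genes a strain difference in expression was not separated from reads assigned to a related gene or lost. The list rose with camera (adjusted p = 0.0128; median 0.12), with adjusted p = 0.712 with an estimated correlation, 0.0533 without C57BL/6J sample 1 and 0.195 without NOD sample 1.

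Metabolic genes changed in single members. Among 21 genes of glycolysis and its control, 0 were higher and 1 lower, the same numbers adjusted over the list alone. Pdk1, the kinase that restrains pyruvate dehydrogenase, fell from 134 ± 4.35 to 33.2 ± 0.687 CPM (log2 fold change -2.02 ± 0.16, adjusted p = 0.000209), whereas Ldhb stood at 281 and 338 CPM (adjusted p = 0.721). The glycolysis list fell with camera (adjusted p = 0.0186; median -0.26), with adjusted p = 0.712 with an estimated correlation, 0.132 without C57BL/6J sample 1 and 0.153 without NOD sample 1. The 24 tested cholesterol genes did not move as a list (camera, adjusted p = 0.652; 0.0129, down, without NOD sample 2). Srebf2 stood at 200 and 180 CPM. Among 83 cytosolic ribosomal protein genes, 0 were higher and 2 lower (the same adjusted over the list alone), Rpl34 (-1.77 ± 0.24, adjusted p = 0.00501) and Rpl29 (-1.32 ± 0.23, adjusted p = 0.0133; 0.137 without C57BL/6J sample 1). The ribosomal list fell with camera (adjusted p = 0.0308; median -0.10), with adjusted p = 0.911 with an estimated correlation and 0.473 without NOD sample 2, and without C57BL/6J sample 1 its direction was up (adjusted p = 0.0533). None of 18 dissociation stress genes passed the test, and 0 did adjusted over the list alone (camera, adjusted p = 0.0797), with Hspa8 at 885 ± 480 and 552 ± 20.9 CPM (adjusted p = 0.574; 0.0248 without C57BL/6J sample 1) and Btg2 at 489 and 475 CPM. The stress list had adjusted p-values of 0.0172 without C57BL/6J sample 1, 0.0121 without NOD sample 2 and 0.0463 with the replicate block, all in the down direction.

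Markers of other cells differed in single members. Of 16 markers of NK, gamma-delta and NKT cells, 1 was higher and 0 lower, and 4 and 0 adjusted over the list alone. Tcrg-C4, a constant segment of the gamma receptor chain, rose from 0.455 to 3.00 CPM (log2 fold change 2.70 ± 0.59, adjusted p = 0.0398; 0.264 without C57BL/6J sample 1), while Trdc stood at 65.3 and 79.6 CPM (adjusted p = 0.884; 0.00979 without NOD sample 1). That list rose with camera (adjusted p = 0.00803; median 0.48), with adjusted p = 0.712 with an estimated correlation and 0.470 without NOD sample 2. Of 10 stromal markers, Col1a2, a fibroblast collagen, passed (1 adjusted over the list alone), with 1 count in C57BL/6J and 134 in NOD, a ratio of 60.73 with a counting interval of 10.72 to 2416 (adjusted p = 0.00959; 0.0611 without C57BL/6J sample 2). Pecam1, which thymocytes also express, stood at 147 and 132 CPM. The stromal list rose with camera (adjusted p = 0.0488; median 0.42), with adjusted p = 0.712 with an estimated correlation and 0.0901, 0.6002, 0.128 and 0.251 without C57BL/6J sample 1, C57BL/6J sample 2, NOD sample 1 and NOD sample 2. Of 19 macrophage and dendritic cell markers, Csf1r, which overlaps Hmgxb3, rose from 0.642 to 3.56 CPM (adjusted p = 0.0233; 0.0717 and 0.146 without C57BL/6J sample 1 or 2) and Apoe fell from 38.4 to 10.7 CPM (adjusted p = 0.00785; 0.0853 without C57BL/6J sample 1), with 2 higher and 1 lower adjusted over the list alone and no shift of the list (camera, adjusted p = 0.199). The 1 tested granulocyte marker, Cxcr2, had 3 counts in C57BL/6J and 166 in NOD, a ratio of 25.08 with a counting interval of 8.433 to 122.8 (adjusted p = 0.0189; 0.117 without C57BL/6J sample 1).

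Of 13 B cell markers none passed, and 0 did adjusted over the list alone (camera, adjusted p = 0.270; 0.00766 without NOD sample 1). Igkc, the kappa light chain, stood at 2.58 ± 2.20 and 32.2 ± 32.0 CPM (adjusted p = 0.332; 1.10e-32 without NOD sample 1, 0.00358 without NOD sample 2 and 0.000281 with the replicate block) and Ighm at 346 and 298 CPM. None of 5 erythroid markers passed or did so adjusted over the list alone (camera, adjusted p = 0.286), with Car2 at 7.82 and 9.86 CPM and Hbb-bs at 2.41 and 4.45 CPM. Of 16 double-negative markers, Cd44 alone passed, also when adjusted over the list alone (list with camera, adjusted p = 0.234), with Myb at 1138 and 1182 CPM. None of 21 mature single-positive markers passed, and 0 did adjusted over the list alone (camera, adjusted p = 0.0797), with Ccr4 at 31.8 and 40.7 CPM. The 37 mitochondrially encoded genes had 0 counts in every library and could not be tested. Genes of the Y chromosome were present in both strains, with Ddx3y at 89.8 and 55.5 CPM (adjusted p = 0.163; 0.00198 without NOD sample 1) and Kdm5d lower in NOD (log2 fold change -0.82 ± 0.17, adjusted p = 0.0283; 0.122 and 0.197 without C57BL/6J sample 1 or 2, and 0.0700 with the replicate block), while Xist, which marks female cells, stood at 0.291 and 0.210 CPM. Of the 5 genes of the sex check 0 were higher and 1 lower, and 0 and 3 adjusted over the list alone.

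Of the 31 lists tested as sets, 13 passed with camera, 7 up and 6 down, and 0 passed with an estimated correlation (lowest unadjusted p = 0.0615, for the GIMAP family). By Fisher's exact test, the class I list alone held more called genes than the other tested genes. With fry 0 passed for movement in 1 direction (lowest adjusted p = 0.229, unadjusted 0.00740, for the mature single-positive markers), and 20 passed for change in either direction.

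Genes that differed between the strains lay side by side on the chromosomes more often than random reassignment gave. Among 11791 protein-coding genes in order, 47 adjacent pairs had both genes called, against 13.4 expected (95% range 7 to 21; p = 1e-04, one-sided permutation test, the smallest that 10000 reassignments can give). Both genes changed in the same direction in 32 pairs (68.1%, against 50.2% under reassignment), with 19 pairs higher, 13 lower and 15 opposite. Runs of 3 genes included Ifi213, Ifi209 and Ifi208, all lower, on chromosome 1 (173.57 to 173.7 Mb), Zfp978, Zfp985 and Zfp979, all higher, on chromosome 4 (147.36 to 147.64 Mb). Another run with 1 direction was Aqp11, Pak1 and Myo7a, all lower, on chromosome 7 (97.72 to 98.12 Mb). On chromosome 2 (71.75 to 72.26 Mb) Itga6 and Rapgef4 rose and Pdk1 between them fell, and at 104.3 to 104.35 Mb of chromosome 7 Trim34b rose between Trim12a and Trim12c, which fell. On chromosome 13 (64.28 to 64.44 Mb) Ctsl, the lysosomal protease cathepsin L, rose from 104 to 247 CPM between Aaed1 and Cdk20, which fell. These 6 runs are all that held 3 called genes, and their members outside the naming rule were named after their values were seen. The share of pairs with the same direction was 42.9% without C57BL/6J sample 1, and the ratio of observed to expected pairs, 3.51 here, was 6.11 without C57BL/6J sample 1, 5.43 without C57BL/6J sample 2, 1.92 without NOD sample 2 and 3.92 with the replicate block, each with the smallest p.

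Called genes were unevenly spread over the chromosomes. On chromosome 13 5.97% of tested genes were called (odds ratio 1.71, Fisher's exact test, adjusted p = 0.0119), on chromosome 1 5.25% (odds ratio 1.49, adjusted p = 0.0395), and on chromosome 5 1.95% (odds ratio 0.501, adjusted p = 0.0109). The number of chromosomes that passed was 3. It was 0 without C57BL/6J sample 1, 0 without C57BL/6J sample 2, 7 without NOD sample 1 and 0 with the replicate block. In a comparison chosen after the values were seen, 31 of 39 called genes on chromosome 17 were higher in NOD (79.5%, Fisher's exact test against the other chromosomes, adjusted p = 0.00772). Fisher's exact test counted genes as independent, whereas called genes lay side by side in excess. This p-value and those of the chromosome shares may therefore be too small. The H2 region (33.97 to 37.48 Mb), which holds the MHC, accounted for 18 higher and 2 lower genes of 141 tested, and the rest of chromosome 17 for 13 higher and 6 lower of 645. The 2 lower genes, also chosen after their values were seen, were Gtf2h4, a subunit of transcription factor TFIIH (log2 fold change -1.23 ± 0.19, adjusted p = 0.00786), and Vars2, the mitochondrial valyl-tRNA synthetase (-0.84 ± 0.18, adjusted p = 0.0353).

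**Figure D3:**
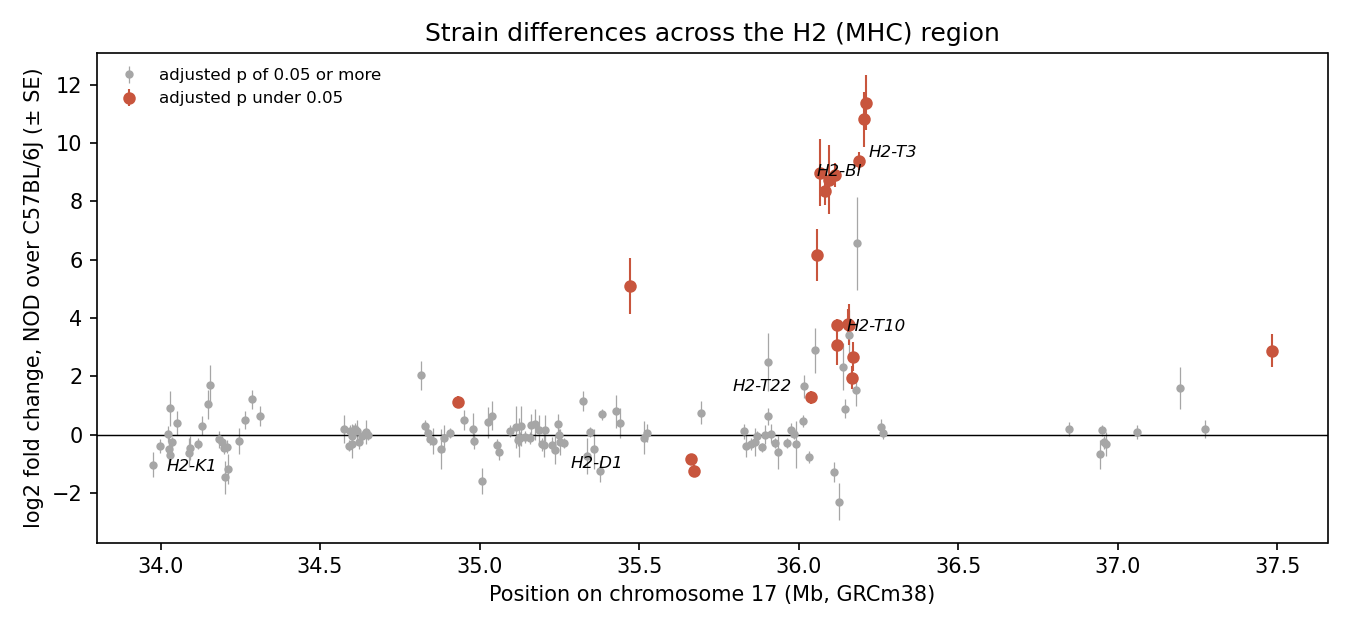
Log2 fold change (NOD over C57BL/6J, with SE) of 141 tested genes against position in the H2 region of chromosome 17 (Mb, GRCm38), with genes of adjusted p under 0.05 in red. H2-T3 at 9.39 and H2-T10 at 3.78 lie among the genes that rose, and H2-K1 and H2-D1 lie below 0 without passing the test.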

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

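Of 196 sets of 4 libraries of 1 strain that were screened for a library far from the other 3 (22 of library measures, 174 of named genes), 4 held one, all of named genes, against 9.8 expected by chance at 1 in 20. The 9.8 treats libraries sharing a B number as independent, so no conclusion was drawn from the comparison. Alpk1 stood at 1.361 CPM in the C57BL/6J library with B number 1 and T number 1, against 2.707 to 2.745 CPM in the other libraries of the strain. Map7 stood at 0.9312 CPM in the NOD library with B number 1 and T number 1, against 3.008 to 3.401 CPM in the other libraries of the strain. Rag1 stood at 10630 CPM in the C57BL/6J library with B number 1 and T number 1, against 8375 to 8513 CPM in the others. Col1a2 stood at 1.927 CPM in the NOD library with B number 2 and T number 2, against 1.025 to 1.093 CPM in the others. No explanation was tested for these values.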

How the results depend on the processing

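The thinning, the covariate, the library exclusion, the crossed pairing and the exclusion of overlapping genes were chosen after seeing the data. The count of called genes (637, with 330 higher and 307 lower) stayed within 1.5 times under DESeq2 size factors (651), upper-quartile factors (622), the DESeq2 Wald test (937), duplicateCorrelation (752), T number 1 libraries (481), protein-coding genes only (497), thinning to equal totals (583) and exclusion of the 2 libraries (847). The calls with duplicateCorrelation leaned to lower genes, with 326 higher and 426 lower, and their directions were not compared by size of change. With the replicate block it was 513, of which 488 were among the 637. With no count filter it was 1188 (646 higher, 542 lower), and with 8 libraries as separate samples 1535 (738, 797), where libraries of 1 sample enter as independent. It was 205 (99, 106) at mean CPM of 5 or more, where 320 of the 637 genes were not tested, and 342 (166, 176) with T number 2 libraries only. It was 399 (212, 187) with a minimum fold of 1.5 and 276 (137, 139) at a threshold of 0.01, both stricter by construction. It was 1271 (543, 728) with the percent of reads outside genes as a covariate, and the cause was not tested. Leaving out each sample gave 256 to 1389 called genes, 124 to 667 higher and 132 to 722 lower, lowest without C57BL/6J sample 1 and highest without NOD sample 2; the lone sample of a strain was assumed to vary like the other strain, and the cause of the range was not tested. None of the 637 genes changed sign in any of these fits.

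The 13 lists past the threshold became 0 with an estimated correlation, which admits that members vary together, and 8 to 11 without each sample. On a scale of signed -log10 p, the proliferation list went from -67.49 without NOD sample 2 to 2.741 without NOD sample 1, the histone list from -16.15 to 3.715 on the same exclusions, and the ribosomal protein list from -11.42 without C57BL/6J sample 2 to 1.693 without C57BL/6J sample 1; these reversed, and the cause was not tested beyond the low proliferation genes of NOD sample 1. The excess of adjacent called genes kept the smallest permutation p, 1e-04, in all 9 alternatives, at ratios of 1.92 to 6.11. The count of 3 chromosomes became 7 with no count filter, 6 with duplicateCorrelation, 6 with the covariate, 1 with T number 2 libraries, 1 with protein-coding genes only, 0 with mean CPM of 5 or more, T number 1 libraries, a minimum fold of 1.5, a threshold of 0.01, thinning or the replicate block (0), and 0 to 7 without each sample; the cause was not tested. The B numbers were not shown to pair the strains, and the crossed pairing gave 768 called genes and 7 chromosomes. Depth limits genes of few counts: bounds rest on 3 counts over samples of 23.81 to 55.647 M reads, and on simulated data 21.5% of genes changed 2-fold were called.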

Other observations

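The tests of reference loss for smaller changes and of strain for the proliferation genes, the thinning, the covariate and the exclusion of overlapping genes were chosen only after the result or the data were seen, as were the genes and the receptor segments of the first paragraphs. Several abundant genes outside the named lists differed between the strains in edgeR, each with all 4 libraries of 1 strain above all 4 of the other. Cmah, the hydroxylase that makes N-glycolylneuraminic acid, rose from 110 ± 3.20 to 604 ± 10.5 CPM in NOD (log2 fold change 2.45 ± 0.17, adjusted p = 6.88e-05). Nav2, a neuron navigator gene, rose from 234 to 579 CPM (1.31 ± 0.19, adjusted p = 0.00520), and the centrosomal genes Cep250 (1.22 ± 0.16, adjusted p = 0.00369) and Pcm1 (0.98 ± 0.18, adjusted p = 0.0159) rose as well. Dock10, an exchange factor for small GTPases, rose from 275 to 492 CPM and Msi2, an RNA-binding protein, from 197 to 343 CPM (adjusted p = 0.0334 and 0.0349). Cfl1, the actin-severing protein cofilin, fell from 745 ± 122 to 325 ± 70.0 CPM (-1.20 ± 0.21, adjusted p = 0.0142), Sema4d, a semaphorin of lymphocytes, fell from 384 to 167 CPM (-1.20 ± 0.16, adjusted p = 0.00339), and Mprip, a myosin phosphatase partner, fell from 551 to 271 CPM (-1.02 ± 0.16, adjusted p = 0.00813). Aqp11, an aquaporin, fell from 379 to 67.7 CPM (-2.49 ± 0.21, adjusted p = 0.000254), and Aim2, the inflammasome sensor of DNA beside the Ifi200 cluster, rose from 6.10 to 38.4 CPM (2.65 ± 0.25, adjusted p = 0.000482).

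Segments of the T cell receptor loci held more called genes than the rest of the tested genes, 14 higher and 5 lower of 187 (10.2% against 3.61%; odds ratio 3.02, Fisher's exact test, p = 6.36e-05). The test counted neighbouring segments as independent, so its p-value may be too small. Of 94 V segments 11 were higher and 4 lower, and of 66 J segments 2 were higher and 0 lower. Trav7-3 rose (log2 fold change 3.10 ± 0.46, adjusted p = 0.00594), Trbj2-5 rose (2.07 ± 0.34, adjusted p = 0.0107), and Trav6-7-dv9 fell from 9.40 to 1.23 CPM (-2.93 ± 0.42, adjusted p = 0.00531). Trav segments exist in similar copies, so a difference between strains in 1 copy was not separated from reads assigned to another.

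The genes called between the strains were weighed against technical sources. Loss of NOD reads on the C57BL/6J reference was predicted to make genes lower in NOD most often where the change is large. Among changes of 4-fold or more 191 of 428 genes were lower (44.6%). Of 209 smaller changes 55.5% were lower (95% interval 48.5% to 62.4%). The odds ratio was 0.647 (0.457 to 0.914, Fisher's exact test, p = 0.0113). Loss of reads would not raise a gene, so it does not account for the 237 large changes that were higher in NOD. For the 191 lower ones it was not excluded, since partial loss that gives small changes would also bring the odds ratio under 1. NOD reads assigned to related genes of the reference could raise a gene, and this was not tested. For the smaller changes reference loss and strain cannot be told apart. The interval of 48.5% to 62.4% holds both an even split and a moderate excess. With all samples thinned to equal totals 309 genes were higher against 330, and with the percent of reads outside genes as a covariate 1271 genes were called against 752 without it, so neither depth nor that share alone accounts for the calls. Variants that differ between the strains may act on these genes, a hypothesis that gene counts alone cannot separate from variants in the reads of single genes.

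The excess of called genes side by side was weighed in the same way. Without overlapping genes there were 40 pairs against a 95% range of 7 to 20 (permutation p = 1e-04, the smallest that 10000 reassignments can give), and without the H2 region and pairs of 1 gene family there were 35 against 6 to 19, so shared reads between overlapping or related genes do not account for the excess. Blocks of strain haplotype that hold several changed genes would also give pairs farther apart, and 143 called pairs lay 0.2 to 1 Mb apart without being adjacent, against 107.1 expected (82 to 135; permutation p = 0.0077). Without pairs of 1 family there were 132 against 105.8 (81 to 134; permutation p = 0.036), and 47.6% of the 143 changed in the same direction. Both counts kept the H2 region, and pairs of H2 genes were not treated as 1 family. How far the excess of distant pairs rests on that region was not tested. Haplotype blocks predict an excess of distant pairs, but these counts do not show that it extends beyond the H2 region. A shared domain of chromatin, the subject of the series, may act as well but was not tested.

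The low proliferation genes of NOD sample 1 were weighed as the last pattern. Strain would lower them in both NOD samples, but in NOD sample 2 their median log2 difference from the C57BL/6J samples was 0.2075 (quartiles 0.115 to 0.309). A bias of the libraries with expression, GC content or gene length does not account for them, since their median difference between NOD samples 1 and 2 was -1.8339, whereas 10000 lists matched on these gave -0.155 to 0.0326 in their central 95% and -0.275 at the lowest. A sort that took fewer cycling blast cells, or a difference in age or health of the mice, may lie behind it; the labels give neither, and no value here separates them.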
